A study of Homo sapiens with 15 samples.

How the data were processed

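RNA sequencing was done on 15 libraries of HaCaT keratinocytes, 3 in each of 5 groups: WT, R820W and KO with vehicle, and WT and R820W with 10 µM mepazine for 24 h. Groups and letters were taken from the sample titles. The authors deposited raw read counts per gene symbol, 1 column per library, with no normalisation. Per the labels' protocols, libraries were made from total RNA with the NEBNext Ultra II Directional kit, which keeps strand. The submitters' processing notes name FastQC, MACS2, DESeq2 and the hg19 build, without roles or versions. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here, so reads from overlapping, antisense or near-identical genes may be shared between symbols. Without the strand setting, counts of a gene and its antisense partner cannot be told apart.

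The table held 28518 symbols, of which 5618 had 0 counts in every library. Of the symbols, 21105 were current, 1809 were older names and 5604 matched neither, with 6.06% of all counts. Values are reported under the symbols as given. The libraries held 20630099 to 26974363 counts. A 5.8S ribosomal RNA symbol took 2.56 to 4.29% of them, and the 10 most abundant symbols 9.76 to 11.7%. The floor of 3 counts corresponded to 0.111 to 0.145 CPM per library. Intervals and floors cover counting error only. The series describes 3 independent experiments, but nothing in the labels says which cultures the libraries of a letter came from. The p-values therefore measure only the spread between these samples, which may in part be technical. Counts of every replicate pair differed by more than sampling noise (3.31 to 14.8 chi-square units per gene over genes with at least 20 counts in the pair), so no library was taken for a copy of another and all 15 were kept. This does not show that they came from separate cultures.

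The tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr (minimum count 10), which left 14971, library sizes were recomputed from these genes, and scaling was by TMM. All 15 libraries entered 1 robust quasi-likelihood fit of edgeR with group as the only term, and 7 contrasts were tested two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes tested. CPM are relative to TMM-scaled library sizes unless stated to be of all counts. With 3 libraries against 3, chance alone leaves the values of the groups without overlap for 10% of genes.

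Gene lists were fixed by name: 34 lists with 842 entries, of which 829 were found. They covered MYC target and ribosome biogenesis, NF-kB, skin antimicrobial, stress keratin, terminal differentiation, basal keratinocyte, G1/S, G2/M, cholesterol, fatty acid, lysosome and TFEB, ATF4, ER chaperone, heat shock, interferon, mesenchymal, NRF2, AHR, ERK and AP-1, hypoxia, p53, YAP, Notch, type 2 and alarmin cytokine, CARD14 complex and MALT1 substrate, histone, oxidative phosphorylation and ribosomal protein genes, and markers of simple epithelium, fibroblasts, melanocytes, leukocytes and endothelium. A further list of 13 mitochondrially encoded names matched no symbol. The 31 lists with at least 3 tested genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over these lists within a contrast. Camera with an estimated correlation and fry were alternatives. Fry tests whether a list moves in 1 direction on balance and does not compare it with other genes. Counts of list members are given over all genes tested and adjusted over the list alone.

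Genes are named by a rule. For each contrast it takes CARD14, MYC, MALT1 and BCL10. It then takes the 8 highest and 8 lowest log2 fold changes among genes with adjusted p under 0.05, a mean of at least 2 CPM in the higher group (any of the 4 groups for the interaction) and no overlap of the 3 values of each group (not required for the interaction). Last, for each list called by camera it takes the 4 members with the smallest adjusted p in the direction of the list, and not all of these are printed. Genes named outside the rule are marked where they appear. The groups, tests, contrasts, lists, naming rule and most alternatives were fixed before the data were examined.

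The edgeR test was tested on simulated data for R820W against WT, drawn from the mean expression of the WT vehicle libraries and the real library sizes, with 200 changed genes in each of 5 draws over 14529 to 14549 genes. It called 40.5% of genes changed by 0.25 on the log2 scale, 64.1% at 0.5, 87.4% at 1 and 95.9% at 2, and 44 of 746 calls (5.90%) were of unchanged genes. With no gene changed, 0 genes were called. Alternatives were a block for the letter, DESeq2, its size factors in edgeR, limma-voom, no filter, a filter of at least 1 CPM in 3 libraries, fits of only the groups compared, and leaving out each library or each letter in turn.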

Results

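Gene expression was measured by RNA sequencing in HaCaT cells, a spontaneously immortalised human keratinocyte line, edited by CRISPR at CARD14. CARD14 is a scaffold protein that joins BCL10 and the paracaspase MALT1 in a complex that activates NF-kB in keratinocytes. Cells were unedited at CARD14 (WT), carried the R820W allele, or were knocked out for it (KO). WT and R820W cells received vehicle or 10 µM mepazine, a phenothiazine MALT1 inhibitor, for 24 h, and KO cells received vehicle. The 5 groups held 3 libraries each, lettered a, b and c. The series describes 3 independent experiments, and the labels do not say that a letter marks 1 experiment or how many edited lines stood for a genotype. Each library held 20630099 to 26974363 counts, so that 3 counts corresponded to 0.111 to 0.145 CPM (counts scaled to library size), and 14971 genes were tested. Values are mean CPM ± SD over 3 libraries, and log2 fold changes are given ± SE from edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p over all genes tested.

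The first principal component held 46.1% of the variance and placed the groups in the order KO and WT with vehicle, WT with mepazine, R820W with vehicle and R820W with mepazine. On this axis the KO libraries overlapped the WT vehicle libraries, which lay between -28.5 and -24.4, while the R820W vehicle libraries lay between 10.2 and 18.5. Replicate pairs differed by 3.31 to 14.8 chi-square units per gene, and no pair agreed within sampling noise. The pair R820W_mepazine a and c differed the most. The mitochondrial transcript MTND5 took 0.209 ± 0.00449% of counts in WT with vehicle and 0.236 ± 0.0103% with mepazine. It took 0.218 ± 0.00744% in R820W with vehicle, 0.259 ± 0.0485% in R820W with mepazine and 0.203 ± 0.00756% in KO.

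**Figure D1:**
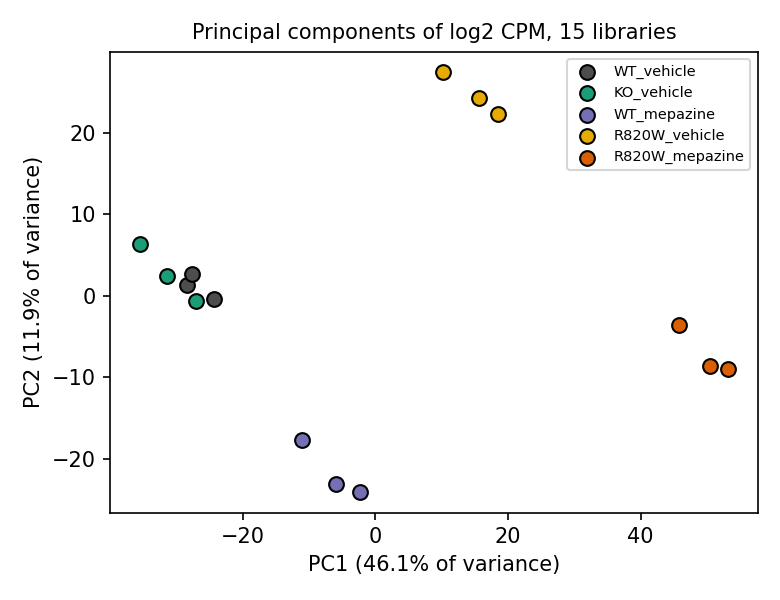
Scores of the 15 libraries on the first 2 principal components of log2 CPM (PC1, 46.1% of the variance; PC2, 11.9%), 1 point per library, coloured by group. The 3 libraries of R820W with mepazine lie at 45.8 to 53.2 on PC1, apart from all others, and KO and WT with vehicle overlap.

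CARD14 mRNA was low in every library and did not differ between genotypes. Its level was 1.67, 1.13 and 1.76 CPM in the WT vehicle libraries a, b and c, 1.62, 1.23 and 1.87 in R820W with vehicle and 1.8, 2.01 and 1.53 in KO. With mepazine it was 1.29, 1.55 and 1.56 in WT and 1.63, 1.49 and 1.7 in R820W. These values rest on 24 to 46 counts per library. The log2 fold change of KO against WT was 0.21 ± 0.213 (adjusted p = 0.886). The mRNA level therefore does not check the knockout: a gene-level count cannot show a small edit, and the labels do not place the edit within the gene.

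MYC, the transcription factor named in the series' title, stood at 197 ± 3.69 CPM in WT and 195 ± 3.73 in KO, and at 159 ± 4.58 in R820W. Mepazine lowered it to 155 ± 5.32 in WT and 98.8 ± 0.181 in R820W. The log2 fold change was -0.31 ± 0.0388 in R820W against WT (adjusted p = 7.61e-07) and -0.01 ± 0.0386 in KO against WT (adjusted p = 0.976). With mepazine it was -0.34 ± 0.0389 in WT (adjusted p = 2.32e-07) and -0.69 ± 0.0399 in R820W (adjusted p = 6.34e-13), and the difference between these responses, -0.34 ± 0.0556, passed the test of the interaction (adjusted p = 0.00125). MALT1 was 58.6 ± 4.12 CPM in WT and 52.1 ± 1.36 in R820W (log2 fold change -0.17, adjusted p = 0.0294), and this call was lost without R820W_vehicle a, WT_vehicle b or R820W_vehicle b (fold changes of -0.20 to -0.11 over the 6 libraries left out in turn). MALT1 also fell with mepazine in R820W (log2 fold change -0.22, adjusted p = 0.00161). BCL10 passed in none of the 7 contrasts, with group means of 38.0 to 40.6 CPM.

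**Figure D2:**
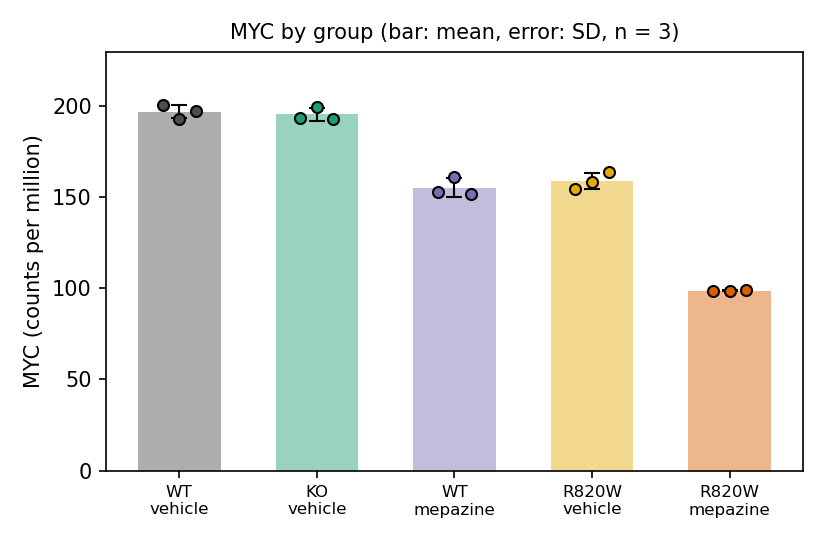
MYC in CPM by group (bars, mean; error bars, SD; points, the 3 libraries). R820W with mepazine stands lowest, at 98.8 CPM, and KO (195 CPM) overlaps WT with vehicle (197 CPM).

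The comparison of R820W with WT under vehicle asked what the allele changes in untreated cells. Interferon-stimulated genes, which encode antiviral effectors, were the clearest group: 27 of 33 rose (28 when adjusted over the list alone), with a median log2 fold change of 0.81. SAMD9L reached 45.7 ± 2.68 against 10.7 ± 1.16 CPM, SAMD9 285 ± 5.53 against 147 ± 9.17 CPM, IFIT3 130.5 ± 4.06 against 75.9 ± 3.9 CPM and IFIT2 115 ± 4.37 against 62.6 ± 3.91 CPM. MYC targets and ribosome biogenesis genes fell: 30 of 59 passed (35 when adjusted over the list alone), among them ODC1, which starts polyamine synthesis (log2 fold change -0.55 ± 0.0455), NPM1 (-0.33 ± 0.0435), TCOF1 (-0.26 ± 0.0419) and DKC1 (-0.25 ± 0.0416). Genes of the basal layer and hemidesmosomes, which anchor keratinocytes to the basement membrane, also fell, 12 of 22 against 2 that rose. COL17A1 fell to 223 ± 6.6 against 315 ± 9.4 CPM, and LAMA3 and TP63 had log2 fold changes of -0.37 and -0.38. Terminal differentiation genes rose (15 of 37), including IVL, a cornified envelope precursor (15.1 ± 0.134 against 7.95 ± 0.846 CPM), KLK5, KLK7 and the lipid transporter ABCA12.

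Of these groups, camera with the preset correlation called the interferon list (adjusted p = 4.92e-49; adjusted p = 2.09e-04 with an estimated correlation), the MYC list (adjusted p = 3.35e-11; adjusted p = 0.113 with an estimated correlation), the basal list (adjusted p = 6.60e-07; adjusted p = 0.0664 with an estimated correlation) and the terminal differentiation list (adjusted p = 5.48e-05; adjusted p = 0.23 with an estimated correlation). The interferon list was the only one of the 31 still called in this comparison with an estimated correlation. The ATF4 and amino acid stress list fell at 20 of 29 genes, with STC2, ATF4, GARS and SLC38A2 at log2 fold changes of -0.50, -0.28, -0.28 and -0.29 (adjusted p = 0.0664 with an estimated correlation). ERK and AP-1 response genes fell at 11 of 25, with 2 that rose. FOSL1, DUSP6 and PHLDA1 fell by 0.49, 0.52 and 0.58 on the log2 scale (adjusted p = 0.0664 with an estimated correlation). Hypoxia and glycolysis genes fell at 9 of 22, with 1 that rose, led by VEGFA (-0.68) and BNIP3 (-1.47) (adjusted p = 0.0664 with an estimated correlation). Heat shock genes fell at 7 of 16 (adjusted p = 0.0664 with an estimated correlation), with AHSA1 at -0.18. NRF2 targets fell at 9 of 24, with 2 that rose and NQO1 at -0.52 (adjusted p = 0.158 with an estimated correlation), and YAP targets at 7 of 14, with 1 that rose and NT5E at -0.78 (adjusted p = 0.413 with an estimated correlation). Cytosolic ribosomal protein genes fell at 15 of 61 (adjusted p = 0.538 with an estimated correlation), with RPL19 at -0.18. Skin antimicrobial genes rose at 5 of 12, with LCN2 at 33.1 ± 1.6 against 8.83 ± 1.64 CPM and S100A9 at 19.2 ± 2.4 against 9.45 ± 1.01 CPM (adjusted p = 0.17 with an estimated correlation). Of the stress keratins 1 of 5 fell, KRT6A, at 405 ± 5.1 against 684 ± 15.3 CPM (adjusted p = 0.0664 with an estimated correlation). KRT6A, KRT6B and KRT6C are near-identical and can share reads.

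Single genes moved much further than these groups. CCDC88C, which binds Dishevelled, stood at 23.7 ± 2.43 against 0.175 ± 0.072 CPM, ALDH1A1, a retinaldehyde dehydrogenase, at 37.3 ± 5.22 against 1.06 ± 0.26 CPM, the metalloprotease MME at 13.3 ± 0.352 against 0.428 ± 0.173 CPM and the glycosyltransferase B3GALT5 at 4.56 ± 0.759 against 0.0544 ± 0.0585 CPM. TNS1, TRIM31 and CNNM1 rose by log2 fold changes of 3.96, 3.82 and 3.68, and the cancer-testis gene CTAG2 to 2.58 ± 0.255 against 0.107 ± 0.0755 CPM. The transcription factor TFCP2L1 fell to 0.137 ± 0.0151 against 8.84 ± 0.702 CPM and the sorting nexin SNX2 to 0.112 ± 0.0892 against 5.4 ± 0.434 CPM. GSPT2, PCDH9, the collagenase MMP1, ADAMTS12, DSEL and CD1D had log2 fold changes from -3.76 to -2.71. CTAG2 and GSPT2 each have a near-identical relative with which reads can be shared. In all, 2879 genes passed, 1590 higher and 1289 lower in R820W, and 484 of them changed at least 2-fold. Leaving out 1 library at a time gave 2071 to 2550. In the same libraries 3 fibroblast markers rose, COL1A1 (2.78 against 1.66 CPM), DCN (2.8 against 0.46) and LUM (2.46 against 0.317), here as CPM of all counts (adjusted p = 0.00312; adjusted p = 0.151 with an estimated correlation). COL1A1 lost its call without R820W_vehicle a, WT_vehicle c or R820W_vehicle c (0.52 to 0.90). COL1A2 and COL3A1, also abundant in fibroblasts, stayed at 0.0142 and 0.027 CPM in R820W. The NF-kB target list moved both ways, with 11 of 35 genes higher and 7 lower (adjusted p = 0.83).

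The comparison of KO with WT asked what loss of CARD14 changes. Few genes differed, 43 higher and 13 lower in KO of 14971, with 14 changed at least 2-fold, and 1141 passed at an unadjusted p under 0.05. At that threshold a share of 0.05 of unchanged genes passes by chance, so many of the 1141 need not be changed. Mesenchymal and TGF-beta response genes rose at 5 of 20 (7 when adjusted over the list alone): fibronectin FN1 at 1994 ± 111 against 1429 ± 59.7 CPM, TNC at 20.9 ± 1.13 against 14.8 ± 1.04 CPM and SPARC at 3.93 ± 0.81 against 1.47 ± 0.211 CPM. TGFBI also rose, and was named after its value was seen. YAP targets rose at 4 of 14 (5 over the list alone), with ANKRD1 at 35.3 ± 4.11 against 20.4 ± 1.78 CPM, NT5E at 36.9 ± 3.55 against 26.1 ± 0.408 CPM, CTGF at 2.96 ± 0.255 against 1.06 ± 0.0926 CPM and CYR61 at 91.5 ± 7.12 against 76.3 ± 3.84 CPM. ATF4 and amino acid stress genes fell, at 3 of 29 over all genes and at 17 when adjusted over the list alone, where 1 gene rose. DDIT4, an inhibitor of mTORC1, stood at 93.6 ± 5.58 against 129 ± 5.69 CPM and PCK2 at 49.4 ± 1.57 against 58.4 ± 2.24 CPM. Of the ERK and AP-1 list only FOSL1 passed over all genes (186 ± 8.57 against 161 ± 4.99 CPM), and 4 of 25 rose when adjusted over the list alone.

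Camera called these lists with both correlations: mesenchymal (adjusted p = 2.27e-13; adjusted p = 0.00237 with an estimated correlation), YAP (adjusted p = 7.52e-12; adjusted p = 0.0497 with an estimated correlation), ATF4 (adjusted p = 2.19e-22; adjusted p = 0.00747 with an estimated correlation) and ERK and AP-1 (adjusted p = 4.83e-07; adjusted p = 0.0348 with an estimated correlation). The interferon list was higher at 2 of 33 genes, IFIT3 (0.23) and RSAD2 (0.52), and at 7 over the list alone (adjusted p = 4.83e-07; adjusted p = 0.0516 with an estimated correlation), and fatty acid synthesis was lower at SCD alone, 938 ± 49.4 against 1149 ± 34.2 CPM, with 2 over the list alone (adjusted p = 4.23e-05; adjusted p = 0.0501 with an estimated correlation). The lysosome list was called higher with 1 gene past the threshold, SQSTM1 (0.32) (adjusted p = 0.00473; adjusted p = 0.256 with an estimated correlation). The MYC list had a median log2 fold change of 0.03, and 0 of its 59 genes passed in edgeR (4 at an unadjusted p under 0.05, 1 in DESeq2, 2 over the list alone). Camera called it with the preset correlation (adjusted p = 9.55e-04; adjusted p = 0.404 with an estimated correlation), and this call was lost without WT_vehicle c (adjusted p = 0.177). With 0 genes past the threshold in edgeR, camera also called 7 other lists, each lost with an estimated correlation. They were NF-kB (adjusted p = 0.256 with an estimated correlation; 6 genes at an unadjusted p under 0.05), skin antimicrobial (adjusted p = 0.256 with an estimated correlation; 2 genes), simple epithelium (adjusted p = 0.167 with an estimated correlation; 3 genes) and G1/S (adjusted p = 0.445 with an estimated correlation; 2 genes), all higher in KO, oxidative phosphorylation (adjusted p = 0.558 with an estimated correlation; 3 genes) and ribosomal protein (adjusted p = 0.628 with an estimated correlation; 3 genes), also higher, and cholesterol synthesis, which was lower (adjusted p = 0.256 with an estimated correlation; 5 genes). In DESeq2 1 ribosomal protein gene and none of the others passed. The preset-correlation calls were lost without KO_vehicle a or WT_vehicle b for NF-kB (adjusted p up to 0.073), WT_vehicle a for skin antimicrobial (0.24), WT_vehicle b for simple epithelium (0.0734) and ribosomal protein (0.096), WT_vehicle b or KO_vehicle c for oxidative phosphorylation (0.325), and WT_vehicle a, KO_vehicle b or WT_vehicle c for G1/S (0.116).

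FNDC1, which has a fibronectin type III domain, was nearly confined to KO among these 2 groups, with 304 counts over the 3 KO libraries against 1 in WT, a ratio of 287 (95% counting interval 51.1 to 11368). TLR4, the lipopolysaccharide receptor, stood at 3.32 ± 0.377 against 1.16 ± 0.14 CPM, the protease ADAMTS12 at 12 ± 0.355 against 4.73 ± 0.489 CPM and the transglutaminase TGM2 at 6.01 ± 0.948 against 2.51 ± 0.405 CPM. IL20RB, a receptor subunit for IL-20 cytokines, fell to 25.1 ± 0.93 against 32.1 ± 1.49 CPM, a call lost without KO_vehicle a (log2 fold changes of -0.40 to -0.33 over the 6 libraries left out in turn), and CBS to 22.4 ± 0.912 against 28.3 ± 2.19 CPM, lost without WT_vehicle a or KO_vehicle a (-0.38 to -0.28). MSRB3, PDE1C, PLEKHH2, IKZF2, SESN2 and SLC6A9 passed with all libraries and each lost its call in 4 or 5 of the 6 fits that left 1 out, with log2 fold changes of 1.40 to 1.75, 0.95 to 1.43, -0.62 to -0.46, -0.42 to -0.32, -0.43 to -0.26 and -0.39 to -0.27. Each of the 6 libraries was among those left out for at least 1 of them. Among the list members named here, calls were lost for FOSL1 without KO_vehicle a, WT_vehicle b or WT_vehicle c (0.17 to 0.24), CYR61 without WT_vehicle a, KO_vehicle a, KO_vehicle b or WT_vehicle c (0.23 to 0.33), PCK2 without WT_vehicle a, KO_vehicle a, WT_vehicle b or KO_vehicle c (-0.27 to -0.22), IFIT3 without KO_vehicle a, WT_vehicle b, KO_vehicle b or WT_vehicle c (0.19 to 0.27) and RSAD2 without WT_vehicle a, KO_vehicle a, KO_vehicle b or WT_vehicle c (0.40 to 0.63), with the range of log2 fold changes over the 6 fits in parentheses. The count of 56 genes fell to 22 without KO_vehicle a, 33 without WT_vehicle b and 36 without WT_vehicle c.

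Of the 56 genes that passed in KO, 40 also passed in R820W against WT: 11 were higher and 5 lower in both genotypes, and 24 moved in opposite directions. Independent lists of these sizes would share 4.57, 1.12 and 5.08. GBP1, SPARC, CALD1 and SAA1 were higher in both, and SCD, IL20RB, CBS and DDIT4 lower in both. FN1 (log2 fold change 0.48 in KO and -1.005 in R820W), ANKRD1 (0.79 and -0.57), ADAMTS12 (1.34 and -3.17) and FOSL1 (0.21 and -0.49) moved apart. GBP1, CALD1 and SAA1 were chosen after their values were seen. Over all 14971 genes the fold changes correlated at r = 0.204 and rho = 0.0662 across genes, which are not independent replicates. In a simulation the WT, R820W and KO vehicle libraries were all drawn from the WT means, with no gene changed. It gave r = 0.524 on average over 20 draws, and 0 shared calls. With no gene changed few or no calls are made at all. The 0 shared calls therefore do not show how far shared WT libraries add to the overlap of groups that did change. The covariance was 0.0321 against a simulated 0.0478, a difference of -0.0158. The 3 WT libraries cannot be split into parts of at least 2. Part of the overlap in the same direction may therefore come from sharing them. Errors in the WT values move both fold changes the same way, so they do not account for the 24 genes that moved apart. KO against WT and mepazine in R820W, which share no library, had 13 genes higher and 5 lower in both and 17 in opposite directions. Independent lists would give 9.49, 3.22 and 13.5 (r = -0.0615 and rho = -0.157 across genes).

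Mepazine was tested in WT cells. MALT1 activity was not measured, so effects of the drug through MALT1 and through other targets are not separated here. Cholesterol synthesis genes, targets of SREBP2, rose almost as a whole (27 of 28), with HMGCS1 at 567 ± 16.8 against 221 ± 8.6 CPM, INSIG1 at 149.6 ± 4.52 against 66 ± 5.65 CPM and FDFT1 at 306 ± 6.14 against 159.9 ± 5.25 CPM. Lysosome genes and targets of TFEB rose at 29 of 36 (30 over the list alone), led by GPNMB (271 ± 23.1 against 52.1 ± 3.06 CPM), the autophagy receptor SQSTM1 (412 ± 14.8 against 185 ± 6.65 CPM) and the sialidase NEU1 (35.6 ± 2.2 against 15.4 ± 1.08 CPM). Fatty acid synthesis rose at 11 of 15, with the desaturase SCD at 2713 ± 75.6 against 1149 ± 34.2 CPM. MYC targets fell at 54 of 59, while 1, SLC29A2, rose, and the median log2 fold change was -0.28. SRM, NOP56, ODC1 and BOP1 had log2 fold changes of -0.47, -0.40, -0.43 and -0.51. SLC29A2 was chosen after its value was seen. NF-kB targets fell at 17 of 35 and rose at 4. Among those that fell, the chemokine IL8 stood at 3.21 ± 0.772 against 10.4 ± 0.538 CPM, MMP9 at 2.51 ± 0.356 against 8.7 ± 1.15 CPM, the NF-kB inhibitor TNFAIP3 at 33.7 ± 3.21 against 64.4 ± 2.08 CPM and TRAF1 at 3.72 ± 0.0607 against 8.98 ± 0.356 CPM.

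Stress keratins fell at 3 of 5, with KRT6A at 390.4 ± 18.7 against 684 ± 15.3 CPM and KRT17 at 461 ± 19.3 against 611 ± 14.9 CPM. ATF4 targets fell at 18 of 29 (22 over the list alone) and rose at 2, and heat shock genes fell at 10 of 16. ERK and AP-1 response genes fell at 12 of 25 and rose at 1, with the EGF receptor ligands AREG, EREG and TGFA at log2 fold changes of -1.09, -0.92 and -0.58 and FOSL1 at -0.68. Simple epithelium markers fell at 4 of 9 and rose at 1, with KRT8 and KRT18 at -0.48 and -0.56. NRF2 targets rose at 14 of 24 and fell at 1, with the ferritin genes FTH1 and FTL at 0.61 and 0.64; both have many pseudogenes that can take reads. Camera called all of these lists with both correlations, with adjusted p = 2.16e-06 with an estimated correlation for cholesterol, 2.12e-04 for lysosome and for fatty acid synthesis, 0.00511 for MYC, 0.0102 for NF-kB, 0.00284 for stress keratins, 0.0102 for ATF4, 0.00827 for heat shock, 0.00603 for ERK and AP-1, 0.0282 for simple epithelium and 0.0108 for NRF2. Calls made with the preset correlation alone were ribosomal protein genes, lower at 43 of 61 (adjusted p = 0.271 with an estimated correlation), the basal list, lower at 10 of 22 and higher at 4 (adjusted p = 0.07 with an estimated correlation), AHR targets, higher at 4 of 8 with CYP1A1 at 0.85 (adjusted p = 0.0579 with an estimated correlation), oxidative phosphorylation, lower at 7 of 41 (adjusted p = 0.565 with an estimated correlation), and the list of the CARD14 complex and MALT1 substrates. That last list was lower at 6 of 21 genes, among them RELB (-0.65) and TNIP1 (-0.32), and higher at 1 (adjusted p = 0.122 with an estimated correlation), and it lost its preset-correlation call without WT_mepazine a (adjusted p = 0.0521). Interferon genes were higher at 8 of 33 and lower at 2 (adjusted p = 0.373 with an estimated correlation), and G1/S genes lower at 6 of 38 and higher at 1 (adjusted p = 0.48 with an estimated correlation). The interferon call was lost without WT_mepazine a, WT_vehicle c or WT_mepazine c (adjusted p up to 0.108), and the G1/S call without WT_mepazine a, WT_vehicle b or WT_mepazine c (up to 0.0908).

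In total 3588 genes passed in WT, 1855 higher and 1733 lower with mepazine, of which 143 changed at least 2-fold. Leaving out 1 library at a time gave 2427 to 3120. Besides GPNMB, the highest folds were in PSG5, FAM49A, PRODH, BLNK, PADI3, FBXO32 and MYLK, at log2 fold changes from 2.46 to 1.50. PSG5 belongs to a family of near-identical genes. The lowest, after MMP9 and IL8, were BMPER (-1.48), SERPINB2 (117 ± 11.2 against 303 ± 5.44 CPM), KRT6C, CXCL1 (-1.28), TRAF1 and IL32 (-1.25). The endothelial cadherin CDH5 also rose with mepazine in WT (log2 fold change 1.14, adjusted p = 0.00321) and in R820W (1.75, adjusted p = 1.18e-05). It was chosen after its values were seen.

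Mepazine was also tested in R820W cells. MYC targets fell at 56 of 59 (57 over the list alone), with a median log2 fold change of -0.52. SRM stood at 65.5 ± 3.48 against 119.8 ± 6.53 CPM, ODC1 at 69 ± 2.7 against 119.7 ± 3.98 CPM, RRS1 at 47.1 ± 1.27 against 81.3 ± 4.12 CPM and NOP56 at 268 ± 0.302 against 432 ± 12 CPM. NF-kB targets fell at 25 of 35 and rose at 5, with IL8 at 2.32 ± 0.262 against 13.8 ± 1.64 CPM, CXCL1 at 2.96 ± 0.179 against 9.71 ± 1.6 CPM and TNFAIP3 at 23 ± 0.946 against 55.8 ± 5.22 CPM. ERK and AP-1 response genes fell at 17 of 25 and rose at 2, with FOSL1 at 44.5 ± 1.55 against 114 ± 1.43 CPM, EREG at 7.47 ± 0.444 against 21.1 ± 0.889 CPM and AREG at 4.27 ± 0.565 against 12.6 ± 0.651 CPM. ATF4 targets fell at 23 of 29 and rose at 4, with CHAC1, which degrades glutathione, at 2.44 ± 0.604 against 11.1 ± 0.256 CPM. Heat shock genes fell at 12 of 16 and rose at 1, with HSPA8 at 2064 ± 62.8 against 3117 ± 73.7 CPM. Cholesterol synthesis genes rose at 27 of 28, with a median of 0.54, lysosome genes at 31 of 36 with 1 that fell, fatty acid synthesis genes at 8 of 15 with 2 that fell, and AHR targets at 5 of 8. HMGCS1 stood at 407 ± 42.6 against 222 ± 4.87 CPM, GPNMB at 363 ± 31.1 against 67.5 ± 5.07 CPM and CYP1B1 at 57.9 ± 2.53 against 39.4 ± 0.442 CPM.

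These 9 lists were called with both correlations, with adjusted p = 0.00182 with an estimated correlation for MYC, 0.0283 for NF-kB and for AHR, 0.0106 for ERK and AP-1, 0.0138 for ATF4 and for fatty acid synthesis, 0.00171 for heat shock, and 0.00123 for cholesterol and for lysosome. Others were called with the preset correlation alone. Replication and G1/S genes fell at 31 of 38 and rose at 1, with RRM2 at -0.46 (adjusted p = 0.119 with an estimated correlation), and G2/M genes fell at 16 of 36 and rose at 2, with CDC20 at -0.37 (adjusted p = 0.419 with an estimated correlation). Ribosomal protein genes fell at 51 of 61 and oxidative phosphorylation genes at 20 of 41 (adjusted p = 0.419 with an estimated correlation for each). ER chaperones fell at 9 of 20, with HSPA5 at -0.32 (adjusted p = 0.214 with an estimated correlation), stress keratins at 2 of 5 (adjusted p = 0.0828 with an estimated correlation), and simple epithelium markers at 5 of 9 with 2 that rose (adjusted p = 0.119 with an estimated correlation). Interferon genes rose at 13 of 33 and fell at 4, with STAT2 at 0.77 and RSAD2 at 0.61 (adjusted p = 0.277 with an estimated correlation). NRF2 targets rose at 10 of 24 and fell at 4 (adjusted p = 0.148 with an estimated correlation), a call lost without R820W_mepazine b (adjusted p = 0.0552). The fibroblast markers LUM, DCN and COL1A1 rose to 11.8, 11 and 6.3 CPM of all counts, beside COL1A2 at 0.0289 (adjusted p = 0.131 with an estimated correlation).

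In all 7013 genes passed in R820W, 3303 higher and 3710 lower with mepazine, and 441 changed at least 2-fold. Leaving out 1 library at a time gave 5997 to 6981. The p53 target TP53INP1 rose to 9.17 ± 1.87 against 1.46 ± 0.53 CPM and its relative TP53INP2 to 4.26 ± 0.975 against 0.801 ± 0.313 CPM. PSG5, PRODH and CYBRD1 rose by log2 fold changes of 2.64, 2.17 and 2.14. JH8, an older name of JRK, rose by 2.81 (adjusted p = 0.0468), and lost its call without R820W_vehicle a, R820W_mepazine a, R820W_vehicle b, R820W_vehicle c or R820W_mepazine c (2.31 to 3.35). IL1A fell to 3.04 ± 0.436 against 10.4 ± 1.25 CPM, KRT81 to 1.98 ± 0.387 against 7.05 ± 0.703 CPM, SERPINB2 to 86.2 ± 5.55 against 265 ± 9.98 CPM, MMP9 by 2.15 and BMPER by 2.01 on the log2 scale. KRT81 has near-identical hair keratin relatives. Mepazine in both genotypes shared 1466 genes that rose and 1587 that fell, against 409 and 429 for independent lists, and 9 moved in opposite directions against 842. Across genes, the fold changes correlated at r = 0.423 and rho = 0.672.

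**Figure D3:**
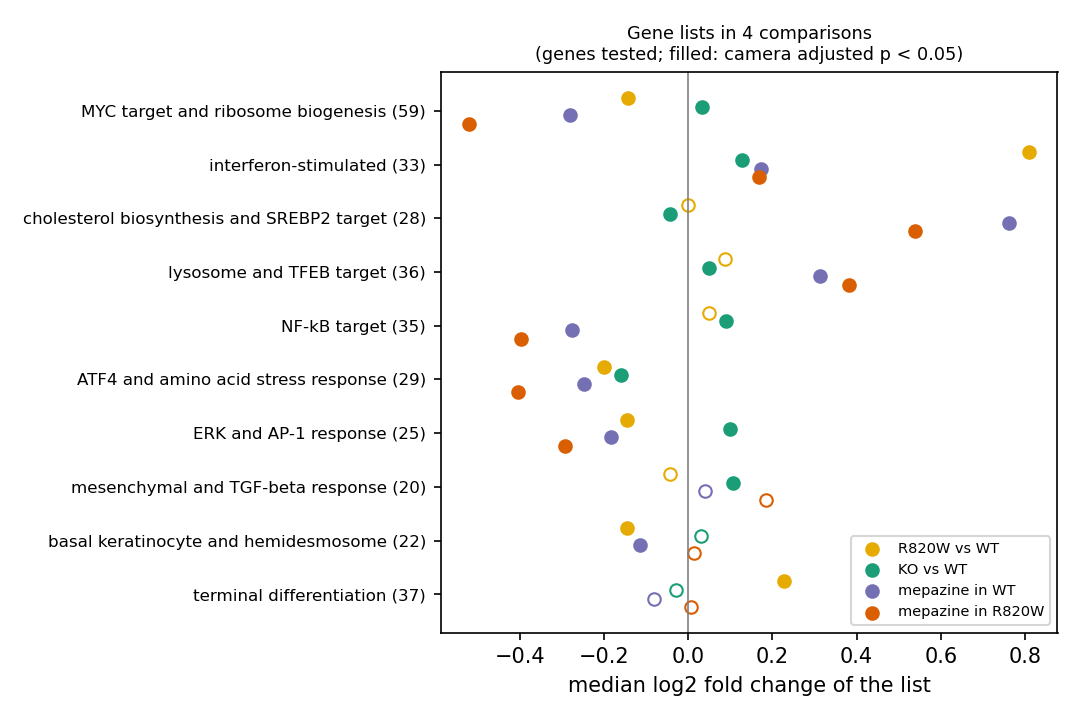
Median log2 fold change of 10 gene lists in 4 comparisons, with the number of genes tested in each list; filled points were called by camera with the preset correlation. The MYC list lies below 0 in R820W against WT and with mepazine in both genotypes, at -0.14, -0.28 and -0.52, and the interferon list lies furthest to the right in R820W against WT, at 0.81.

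The interaction tested whether the response to mepazine differed between R820W and WT, and a negative value means a lower value of the response in R820W. It passed at 577 genes, 118 positive and 459 negative, of which 18 differed at least 2-fold. MYC targets had lower values at 24 of 59 genes and at 51 when adjusted over the list alone, with a median of -0.24. RRS1, SRM, the folate carrier SLC19A1 and ODC1 differed by -0.43 ± 0.0647, -0.41 ± 0.0674, -0.57 ± 0.0996 and -0.37 ± 0.0656. Cholesterol synthesis genes, which rose in both genotypes, also had negative values, at 13 of 28 (17 over the list alone), with ACAT2, HMGCS1, MSMO1 and SQLE at -0.49, -0.49, -0.50 and -0.34. Heat shock genes were negative at 5 of 16 (10 over the list alone), with HSPA8 at -0.31 and FKBP4 at -0.29. These 3 lists were called with both correlations (adjusted p = 0.014 with an estimated correlation for MYC, 0.0109 for cholesterol and 0.00979 for heat shock).

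Lists called with the preset correlation alone were negative for G1/S (5 of 38, 18 over the list alone; adjusted p = 0.111 with an estimated correlation), G2/M (4 of 36, 12 over the list alone; adjusted p = 0.176 with an estimated correlation), and ATF4 (8 of 29, with 2 positive; adjusted p = 0.151 with an estimated correlation), with CHAC1 at -1.34 ± 0.179 and STC2 at -0.62 ± 0.106. The same held for ERK and AP-1 (7 of 25, with 1 positive; adjusted p = 0.116 with an estimated correlation), where FOSL1 differed by -0.67 ± 0.0652 and DUSP6 by -0.34 ± 0.0717, lost without R820W_vehicle b (-0.38 to -0.30), and for fatty acid synthesis (3 of 15; adjusted p = 0.115 with an estimated correlation). Basal keratinocyte genes had positive values at 4 of 22: ITGB4 (0.30), LAMB3 (0.28), COL7A1 (0.33) and COL17A1 (0.21) (adjusted p = 0.0861 with an estimated correlation). COL17A1 lost its call in 11 of the 12 fits that left out 1 library (0.18 to 0.25), all but that without R820W_mepazine b, and COL7A1 without WT_vehicle a, WT_mepazine b, R820W_vehicle b, WT_vehicle c or R820W_mepazine c (0.24 to 0.41), LAMB3 without WT_mepazine a or R820W_vehicle b (0.24 to 0.33) and ITGB4 without R820W_vehicle b (0.26 to 0.34). Lysosome genes were positive at 3 of 36 (adjusted p = 0.255 with an estimated correlation). The NF-kB list was negative at 5 of 35 (adjusted p = 0.365 with an estimated correlation), and its call was lost without WT_vehicle b, WT_mepazine b, R820W_mepazine b or R820W_vehicle c (adjusted p up to 0.147). Oxidative phosphorylation was negative at 1 of 41 (adjusted p = 0.479 with an estimated correlation; 0.15 without R820W_mepazine a). AHR targets were positive at 1 of 8, CYP1B1, which lost its call in 10 of 12 fits without WT_vehicle a, WT_mepazine a, R820W_vehicle a, R820W_mepazine a, WT_vehicle b, WT_mepazine b, R820W_vehicle b, R820W_mepazine b, WT_vehicle c or R820W_vehicle c (0.24 to 0.31) (adjusted p = 0.131 with an estimated correlation; up to 0.0583 without R820W_mepazine b or R820W_vehicle c). The terminal differentiation, fibroblast and histone lists were called positive with 0 genes past the threshold in edgeR and DESeq2 (for terminal differentiation 5 positive and 1 negative at an unadjusted p under 0.05, for fibroblast 0 and for histone 1 positive). With an estimated correlation these 3 had adjusted p = 0.479, 0.255 and 0.365, and each lost its call in 5 to 7 of the 12 fits that left out 1 library, at adjusted p up to 0.165, 0.0677 and 0.186. The libraries were WT_mepazine a, WT_mepazine b, R820W_vehicle b, WT_vehicle c and R820W_mepazine c for terminal differentiation, WT_vehicle a, WT_mepazine a, WT_mepazine b, R820W_vehicle b and WT_vehicle c for fibroblast and WT_vehicle a, WT_mepazine a, R820W_vehicle a, R820W_vehicle b, R820W_mepazine b, WT_vehicle c and R820W_mepazine c for histone. The stress keratin list was not called (test positive, adjusted p = 0.0902), and its median (-0.07) and mean (-0.94) were negative. No called list in any contrast had a median, mean and test that differed in sign. The count of 577 ranged from 123 without R820W_vehicle b and 146 without WT_mepazine b to 1343 without R820W_mepazine b. It was 339 without WT_vehicle a, 335 without WT_mepazine a, 366 without R820W_mepazine a, 360 without WT_vehicle b, 241 without WT_vehicle c, 332 without R820W_vehicle c and 227 without R820W_mepazine c.

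**Figure D4:**
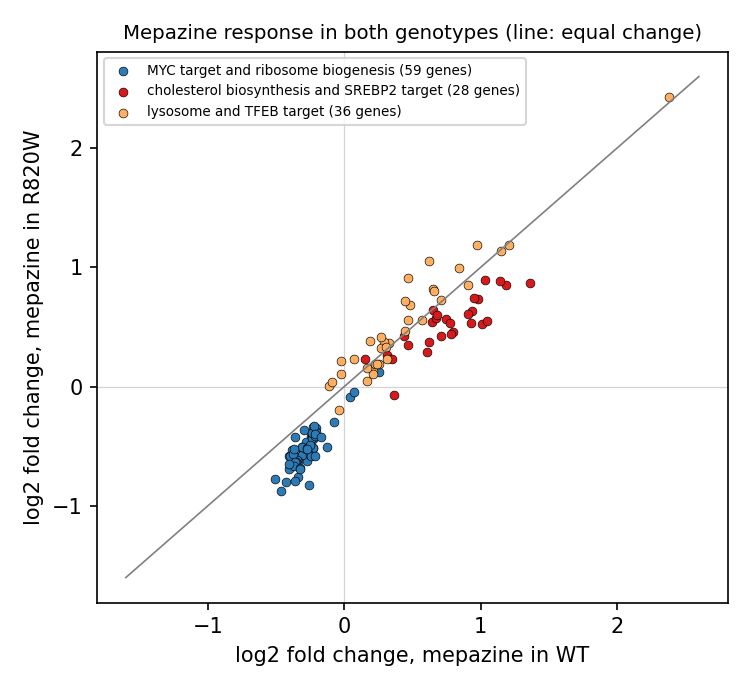
Log2 fold change with mepazine in WT (horizontal) and in R820W (vertical) for the genes of 3 lists, 1 point per gene; the line marks equal change. The MYC targets all lie below the line, with list medians of -0.28 in WT and -0.52 in R820W, and the cholesterol genes lie mostly below it, with medians of 0.76 and 0.54.

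KO and R820W, the edited genotypes, were also compared directly under vehicle. Interferon genes were lower in KO at 25 of 33, with SAMD9L at 12.1 ± 0.985 against 45.7 ± 2.68 CPM and IFI44 at 14.7 ± 0.33 against 31.2 ± 0.875 CPM, and ERK and AP-1 response genes were higher at 13 of 25, with FOSL1 at 186 ± 8.57 against 114 ± 1.43 CPM. Mesenchymal genes were higher at 9 of 20 and lower at 3, with FN1 at 1994 ± 111 against 712 ± 44.2 CPM and INHBA at 11.7 ± 0.457 against 6.2 ± 0.437 CPM, and basal keratinocyte genes were higher at 14 of 22 and lower at 1, with COL17A1 at 322 ± 9.62 against 223 ± 6.6 CPM. These 4 lists were called with both correlations (adjusted p = 0.00162 with an estimated correlation for interferon, 0.0232 for ERK and AP-1, and 0.0473 for mesenchymal and for basal). MYC targets were higher in KO at 45 of 59 (50 over the list alone), with ODC1 at 197 ± 6.72 against 119.7 ± 3.98 CPM (adjusted p = 1.54e-13; adjusted p = 0.068 with an estimated correlation). YAP targets were higher at 9 of 14 and lower at 1, with ANKRD1 at 35.3 ± 4.11 against 13.7 ± 1.6 CPM (adjusted p = 0.122 with an estimated correlation), and hypoxia genes higher at 11 of 22 (adjusted p = 0.0674 with an estimated correlation). Terminal differentiation genes were lower at 18 of 37 and higher at 1, with IVL at -0.85 (adjusted p = 0.268 with an estimated correlation). Heat shock genes (10 of 16; adjusted p = 0.0558 with an estimated correlation), stress keratins (3 of 5; adjusted p = 0.0671 with an estimated correlation) and ribosomal protein genes (30 of 61; adjusted p = 0.473 with an estimated correlation) were higher. So were NRF2 targets (6 of 24, with 4 lower; adjusted p = 0.122 with an estimated correlation) and oxidative phosphorylation genes (6 of 41; adjusted p = 0.653 with an estimated correlation), whose preset-correlation call was lost without R820W_vehicle c or KO_vehicle c (adjusted p up to 0.0748). The fibroblast markers were lower at 3 of 3 (adjusted p = 0.169 with an estimated correlation). Of 3960 genes that passed, 1987 were higher and 1973 lower in KO, and 558 differed at least 2-fold (2918 to 3652 genes with 1 library left out). FNDC1 was at least 102-fold higher in KO, taken against 3 counts over the R820W group, where it had none. TLR4 and PDE1C had 1 count each over the R820W group and count ratios of 239 (95% interval 42.5 to 9486) and 194 (34.4 to 7700). CCDC88C, ALDH1A1 and MME were lower in KO, by log2 fold changes of -6.46, -5.63 and -4.50.

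R820W and WT were last compared under mepazine. MYC targets were lower in R820W at 57 of 59, with a median log2 fold change of -0.38 and ODC1 at 69 ± 2.7 against 130.1 ± 8 CPM, and interferon genes were higher at 29 of 33, with a median of 0.78 and RSAD2 at 22 ± 0.708 against 5.98 ± 0.294 CPM. ATF4 targets were lower at 22 of 29 and higher at 1, ERK and AP-1 response genes lower at 16 of 25 and higher at 3, and heat shock genes lower at 12 of 16. FOSL1 had a log2 fold change of -1.17 ± 0.048, while STC2 stood at 12.7 ± 0.438 against 27.7 ± 1.67 CPM and HSPH1 at 383 ± 20.5 against 503 ± 18.1 CPM. These 5 lists were called with both correlations (adjusted p = 0.0217 with an estimated correlation for MYC, 0.00134 for interferon, 0.0407 for ATF4 and for ERK and AP-1, and 0.0073 for heat shock). Cholesterol genes were lower at 20 of 28 and higher at 2 (adjusted p = 0.0509 with an estimated correlation), and terminal differentiation genes higher at 19 of 37 and lower at 3, with IVL at 32 ± 3.68 against 13.1 ± 1.1 CPM (adjusted p = 0.202 with an estimated correlation). Of the lists called with the preset correlation alone, G1/S (27 of 38, with 1 higher), G2/M (19 of 36), fatty acid synthesis (8 of 15, with 1 higher), ER chaperone (10 of 20), NRF2 (12 of 24, with 4 higher), hypoxia (12 of 22, with 1 higher), oxidative phosphorylation (17 of 41) and ribosomal protein genes (30 of 61) were lower in R820W. Skin antimicrobial (6 of 12), lysosome (21 of 36, with 4 lower) and fibroblast genes (3 of 3) were higher, LUM and DCN among them at 11.8 and 11 CPM of all counts. With an estimated correlation these 11 had adjusted p = 0.0737 to 0.653. In total 6717 genes passed, 2909 higher and 3808 lower in R820W, and 733 differed at least 2-fold (5617 to 6839 with 1 library left out). The secretory immunoglobulin receptor PIGR reached 27.3 ± 5.46 against 1.43 ± 0.239 CPM, while the peroxidase PXDN fell to 0.258 ± 0.0988 against 2.42 ± 0.338 CPM. R820W against WT shared 1353 higher and 1134 lower genes between vehicle and mepazine, against 309 and 328 for independent lists, with 11 in opposite directions against 655. These are separate libraries, and the fold changes correlated at r = 0.631 across genes.

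Some lists passed in none of the 7 contrasts. The p53 target list had adjusted p from 0.62 to 0.943, the Notch target list 0.19 to 0.899, the type 2 and alarmin cytokine list 0.0764 to 0.806 and the melanocyte list 0.309 to 0.981. In the alarmin list 4 of 14 genes were expressed enough to test, and in the Notch list 5 of 9. Leukocyte and endothelial markers had 2 tested genes each and were not tested as lists. CD68 and CD14 reached group means of at most 4.96 and 1.56 CPM of all counts, and VWF at most 1.26. CDH5 reached a group mean of 27 CPM of all counts and rose with mepazine in both genotypes. CD14 was higher in R820W than in WT (log2 fold change 1.12, adjusted p = 0.00771); it was chosen after its value was seen.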

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

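The tests of fibroblast genes, of a uniformly stronger response and of MALT1 activity were chosen only after the results they bear on were seen, and so was the idea of a GC, length or expression trend, though its bounds were set before it was run. A test of a scaling shift common to all genes was also run and then set aside after its result was seen: the median interaction of the MYC list (-0.24) lay below the lower quartile of all genes (-0.14), whose median was -0.03.

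The response to mepazine differed between R820W and WT by the interaction test at 577 genes, and at MYC by -0.34, a call kept in all 12 fits that left out 1 library. Among the positive differences were MMP1 2.12 (lost without WT_mepazine b, R820W_vehicle b or R820W_mepazine c; 1.63 to 2.64), LBH 1.79 (lost without WT_vehicle a, WT_mepazine a, WT_vehicle b, WT_mepazine b, R820W_vehicle b, WT_vehicle c, R820W_vehicle c or R820W_mepazine c; 1.46 to 2.06), NUTM2D 1.43 (lost without WT_vehicle a, WT_mepazine b, R820W_vehicle b, WT_vehicle c, R820W_vehicle c or R820W_mepazine c; 1.21 to 1.92), TP53INP1 1.34 (lost without WT_vehicle a, WT_mepazine a, R820W_mepazine a, WT_vehicle b, WT_mepazine b, R820W_vehicle b, WT_vehicle c, R820W_vehicle c or R820W_mepazine c; 1.09 to 1.61), DAPK2 1.22 (lost without WT_mepazine b, R820W_vehicle b or WT_vehicle c; 1.02 to 1.39), L1CAM 1.12 (lost without WT_vehicle a, R820W_vehicle a, R820W_mepazine a, WT_vehicle b, WT_mepazine b, R820W_vehicle b, R820W_vehicle c or R820W_mepazine c; 0.82 to 1.33), DNAL4 1.10 (lost without WT_vehicle a, WT_mepazine a, R820W_mepazine a, WT_vehicle b, WT_mepazine b, R820W_vehicle b, WT_vehicle c, WT_mepazine c, R820W_vehicle c or R820W_mepazine c; 0.89 to 1.22) and FAT3 0.99 (lost without WT_mepazine a, R820W_mepazine a, WT_vehicle b, WT_mepazine b, R820W_vehicle b, WT_vehicle c or R820W_mepazine c; 0.85 to 1.15), as log2 values with the range over the 12 fits. The negative ones were CHAC1 -1.34, ATP8A2 -0.88 and TMEM171 -0.69, all kept in the 12 fits, and ANXA10 -1.21 (lost without WT_mepazine a, R820W_mepazine a, WT_vehicle b, WT_mepazine b, R820W_vehicle b, WT_vehicle c or R820W_vehicle c; -1.43 to -1.05), KRT81 -1.15 (lost without WT_mepazine a, WT_mepazine b or R820W_vehicle b; -1.30 to -0.96), SPRY4 -0.94 (lost without WT_mepazine a, WT_vehicle b, WT_mepazine b, R820W_vehicle b, WT_vehicle c or R820W_mepazine c; -1.13 to -0.78), IL8 -0.86 (lost without WT_vehicle a, R820W_mepazine a, WT_vehicle b, WT_mepazine b, R820W_vehicle b, WT_vehicle c, R820W_vehicle c or R820W_mepazine c; -1.02 to -0.66) and IL1A -0.84 (lost without R820W_mepazine a, R820W_vehicle b, R820W_vehicle c or R820W_mepazine c; -0.94 to -0.70). NUTM2D and KRT81 have near-identical relatives.

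By the same test the median interaction of gene lists was -0.24 for MYC targets, -0.25 for cholesterol, -0.19 for heat shock, -0.16 for ERK and AP-1, -0.15 for NF-kB, -0.14 for G1/S, -0.14 for G2/M, -0.13 for ATF4, -0.13 for fatty acid synthesis and -0.089 for oxidative phosphorylation. It was 0.12 for basal keratinocyte, 0.13 for AHR, 0.10 for terminal differentiation, 0.049 for lysosome, 0.17 for histone and 0.99 for fibroblast genes. MYC, cholesterol and heat shock were the lists still called with an estimated correlation.

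Of 100 splits of the 12 libraries of the interaction, 8 called 577 genes or more, the real split included. The highest other split called 5228, several times the real count, which points to a structure of the samples: the 7 others that reached 577 were among the 17 that kept the treatment groups of 1 genotype, and so set its mepazine response against mixed groups. The 82 that kept neither called at most 1, but mixed both treatments within their groups. As the splits carry the response to mepazine itself, this count does not decide whether chance can be excluded. For the 6 other contrasts, 10 splits are too few for a share under 0.05; 1 of 10 splits reached the real count in each. The real counts were 2879 for R820W against WT, 3588 and 7013 for mepazine in WT and R820W, 3960 for KO against R820W and 6717 for R820W against WT under mepazine, with 0 for the highest other split, and 56 for KO against WT, with 1.

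R820W differed from WT at 2879 genes and KO at 56. Changes of copy number could shift neighbouring genes together, but 0% of the called genes lay in windows of 51 genes with a median shifted by 0.2, over 13476 placed genes, and window medians ran from -0.12 to 0.19. Shorter segments and shifts under 0.2 are not excluded, as the test could not see them. All windows of chromosome 15 (median 0.094) lay above 0, the highest at 0.19, and all of chromosome 13 (median -0.044) below it. Under mepazine, in separate libraries, the medians of R820W against WT were 0.089 for chromosome 15 and -0.11 for chromosome 13. Chromosomes 8 (-0.10), 5 (-0.098), 18 (-0.091) and 19 (0.082) had medians of like size there, so chromosome 13 did not stand out. The median of chromosome 15 was -0.12 in KO against R820W and -0.014 in KO against WT. For chromosome 13 these medians were 0.041 and -0.0062, and for chromosome 5 they were 0.066 and 0.030. Fibroblasts mixed into the cultures are argued against by COL3A1, the higher of COL1A2 and COL3A1, at 0.972% of the level of COL1A1. Whether the allele or the separate derivation of a line sets the difference stays open, since the number of lines per genotype is not in the labels.

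MYC targets fell more under mepazine in R820W. No single library set this: the median interaction over the fits that left out 1 library was at most -0.21. A trend with GC content, transcript length and expression held 5.15% of the variance over 13366 genes. Its removal moved the median of the list from -0.24 to -0.18, below the lowest of 1000 random lists (-0.07). The random lists were drawn gene by gene and lack the correlation between genes of a list. A list of genes that move together could lie below them for any cause. A response stronger by 1 factor at all genes is argued against by the cholesterol list, which rose with mepazine and had a median interaction of -0.25. Of the other lists that rose in WT and were called in the interaction, fatty acid synthesis was negative (-0.13), and lysosome (0.049) and AHR (0.13) were positive. Of those that fell in WT and were called, all but the basal keratinocyte list (0.12) were negative. A response stronger at many genes, though not at all, is therefore not excluded. A response of MYC targets that depends on the allele is a hypothesis that these tests leave open, as is a difference between lines, which was not tested.

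Interferon-stimulated genes were higher in R820W. No single library set this, as the lowest median over the 6 fits that left out 1 was 0.76. If MALT1 activity kept them high and mepazine blocked it, mepazine could be expected to lower them, but in R820W their median log2 fold change with mepazine was 0.17. In WT the list also rose with mepazine, with medians of 0.12 to 0.20 over fits that left out 1 library. The R820W value alone therefore does not decide. The camera call of the list in WT was lost in 3 of these 6 fits (adjusted p up to 0.108). With an estimated correlation, camera called the list with mepazine in neither genotype. The interaction did not call the list (camera, adjusted p = 0.155). Under mepazine it stayed higher in R820W than in WT, with medians of 0.76 to 0.82 over such fits. How far MALT1 was inhibited was not measured. Activity of CARD14 apart from MALT1, and a difference between lines, stay open and were not tested. The list was also higher in KO than in WT, with medians of 0.11 to 0.16 over fits that left out 1 library. That camera call was lost with an estimated correlation.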

How the results depend on the processing

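The block for the overlap of R820W against WT with and without mepazine, and leaving out libraries for lists other than MYC, were chosen after seeing the data. The letters were not treated as pairs, since 5 of 30 same-letter correlations of deviations exceeded 0.1 (-0.027 to 0.16). Of the 30, 27 were above 0, the means per 2 groups were all positive (0.0294 to 0.092), and 9 of 15 libraries correlated best with their own letter. These values point to a weak effect shared within a letter, which the main fit does not take into account. With the replicate block, calls rose to 103 in KO against WT (56 shared) and 1401 in the interaction (576 shared), and shared same-direction calls to 32 for R820W with KO (from 16) and 29 for KO with mepazine in R820W (from 18); the other counts of calls and overlaps stayed within 1.5 times. With this block the G1/S list for mepazine in WT (adjusted p = 0.0515), the NF-kB (0.0683) and histone (0.0672) lists in the interaction, RPL38 in R820W against WT and JH8 for mepazine in R820W were no longer called. Newly called were the lysosome list in R820W against WT (0.0453), the skin antimicrobial list in KO against R820W (0.0199), the YAP list in R820W against WT under mepazine (0.0367), KRT6C in R820W against WT, TCOF1, ODC1, AARS, DDX58, JUN and RPS14 in KO against WT, and KLK13, IVL, PPL and HSD17B12 in the interaction. The calls of the other 211 list results and 554 results of named genes did not change. Without a filter the interaction called 894 (559 shared). Leaving out a library or a letter gave 1369 to 2550 calls in R820W against WT, 12 to 53 in KO against WT, 1492 to 3120 for mepazine in WT, 59 to 1343 in the interaction and 2384 to 3652 in KO against R820W. Fewer libraries mostly make fewer calls, but the interaction rose from 577 to 633 without WT_mepazine c and to 1343 without R820W_mepazine b. R820W against WT under mepazine rose from 6717 to as many as 6839 with 1 library left out. These rises were not explained, and their cause was not tested. DESeq2, its size factors, limma-voom, the stricter filter and fits of only the groups compared kept all 7 counts within 1.5 times. The balance of higher and lower genes was less stable. With DESeq2's size factors in edgeR it was 1496 higher and 1458 lower in R820W against WT, 1724 and 1907 for mepazine in WT and 2270 and 1835 in KO against R820W, and with DESeq2 it was 1305 and 1320, 1470 and 1788, and 2088 and 1610, so the balance in these 3 contrasts depended on the choice of method. The MYC list lost its call with an estimated correlation in R820W against WT (adjusted p = 0.113), KO against WT (0.404; fry 0.223; 1.58e-06 to 0.177 with 1 library left out, the highest without WT_vehicle c) and KO against R820W (0.068). The ribosomal protein list in the interaction (adjusted p = 0.937) turned to a lower call without R820W_mepazine c (0.00206) and to a higher call without R820W_mepazine a (0.0033), with 0.00206 to 0.995 over the 12 fits; the cause was not tested. Of 217 list results, 77 lost their call with an estimated correlation and 140 kept their side. With fry 17 lost a call, 36 gained one and 164 did neither. For named genes, 325 of the fits that left out 1 library lost a call, 6 gained one and 3551 did neither. With DESeq2, 5 results of named genes lost a call, 3 gained one and 528 did neither. With its size factors in edgeR, 3 lost a call and 564 did not change. At this depth genes with both groups near the floor of 0.111 to 0.145 CPM give no usable fold, and a fold with 1 group near it rests on few counts.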

Other observations

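The KO and R820W lines differed in opposite directions from WT at 24 of the 40 genes that passed in both. SNX2, which sorts endosomal cargo, stood at 11.3 ± 0.293 CPM in KO and 0.112 ± 0.0892 in R820W against 5.4 ± 0.434 in WT. The log2 fold changes in KO and R820W were 1.12 and -2.29 for CPNE8, 0.41 and -1.46 for BASP1, and 0.96 and -0.37 for LCP1, which bundles actin. TMEM200A (0.99 and -1.82) and SNX10 (0.62 and -0.95) moved in the same 2 ways. CPNE8, BASP1, LCP1, TMEM200A and SNX10 were chosen after their values were seen.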
